A study of Mus musculus with 7 samples.

How the data were processed

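RNA of the left ventricle of 7 male mice aged 21 months, 3 labelled eNOS knockout and 4 labelled wild type, was measured on Affymetrix MOE430A arrays, 1 per mouse. Per the labels, total RNA was extracted; the software, background correction and scaling behind the values are not given in the sources used here. The deposited table holds 22690 probe set intensities per array on a linear scale. From the values, the authors' intensities had been brought to nearly the same level on each array (2% trimmed means within 5.33%, with a tolerance of 10%), showed no subtraction of background (lowest value 86.5 to 92.3) and stopped at an upper limit on each array. Of the probe sets, 49.9% had an equal value on at least 2 arrays. Background and upper limit both make differences smaller than they are. The deposited experiment sheets, text files written by the scanner workstation per the file headers and used here as other information with no measurement, gave the hybridization days, which were coded 1 to 4 from the earliest and coincided with 4 chip lots. Day 1 held knockout M140 and wild-type M128, day 2 wild-type M125, day 3 knockout M4 and M10, and day 4 wild-type M23 and M158. A comment on the sheet of M23 says that a first and a second processing were combined.

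The 64 control probe sets were left out, which left 22626. A platform table of unstated date named exactly 1 gene for 20380 of them, several for 691, which were not named, and none for 1555, which are unnamed here. Of the named probe sets, 20351 matched the GRCm38.p6 gene table by gene number. That table changed no symbol; it was used for gene order, and none of its coordinates is given. Values were used as deposited and taken as log2(intensity + 16), so that log2 differences understate changes of dim probe sets. A probe set was tested if it lay above the 40th percentile of its own array on at least 3 arrays, which kept 13836. A gene was represented by its tested probe set with the highest mean over all 7 arrays (8869 genes), and probe sets of a gene that disagree are stated. Arrays were checked for duplicates: pairs correlated at 0.946 to 0.986, and the pair with most equal values shared 7.18% of them exactly.

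The knockout was compared with the wild type by limma 3.58.1 (lmFit and eBayes with trend, two-sided) in R 4.3.3, with no covariate, Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Adjusted p-values of single probe sets are limma's. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 33 lists (22 of heart gene groups and 11 of cell type markers). Camera with an estimated correlation and fry stand beside it. Members were also adjusted over the list alone. Single values were compared by exact two-sided permutation tests over the 35 splits of 7 arrays, for which the smallest p is 0.0286. The genes to name were fixed before the data were examined: Nos3; the 10 genes with the smallest p in each direction among those whose groups do not overlap, since none passed the threshold; the 3 members with the smallest p of each called list; and Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Pdk4, Ucp3, Col1a1 and Col3a1. Ppargc1a, Pln and members that passed over a list alone fall outside that rule and were chosen after their values were seen. Mouse numbers are not shared between the groups, so that nothing is paired.

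The fit was tested on simulated data of this comparison with 200 of 13836 probe sets changed. It recovered 75.5%, 92% and 96.5% of changes of 1, 1.5 and 2 on the log2 scale, with 7, 12 and 9 false calls. Of unchanged probe sets, 5.35% had an unadjusted p under 0.05. The simulated noise was independent between probe sets and arrays, with no effect of day or tissue and no upper limit. These shares may therefore not hold for the real arrays. Over the 8869 genes, a shift of -0.40 of the fatty acid oxidation list was called in 50 of 50 simulations of the same kind. With no change but a true inter-gene correlation of 0, 0.1, 0.2 and 0.4 among its members, camera's preset setting gave that list an unadjusted p under 0.05 in 4%, 23%, 43% and 50% of 100 simulations. Alternatives fixed beforehand were the offset (1 and 64), quantile normalization, no filter, the 60th percentile, eBayes without trend, array weights, a threshold of 0.10, an unadjusted p under 0.05 with a 1.5-fold difference, hybridization day as a fixed block, all probe sets of a gene or their mean, the estimated correlation, fry, and leaving out each array. Added after the data were seen were normexp background correction (offset 50), hybridization day as a random block, for lists the day block, eBayes without trend, array weights and the mean of all probe sets, covariates (Myl7 or the Gapdh ratio), probe sets below the upper limit, and leaving out M23 with M158 or M10 with M125. The Gapdh ratio divides the 5' by the 3' control probe set of Gapdh. The 3' one was at or near the upper limit on every array, so that each ratio is an upper bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.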

Results

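Left ventricles of male mice aged 21 months were profiled on single-colour oligonucleotide arrays of the MOE430A design, with 1 array per mouse. The labels name 3 mice lacking endothelial nitric oxide synthase (eNOS, the enzyme of blood vessel lining that makes nitric oxide, encoded by Nos3), numbered M4, M10 and M140. They name 4 wild-type mice, numbered M23, M125, M128 and M158. The labels give the purpose as finding the transcripts that accompany failing heart function in old eNOS knockout males. A keyword also names exercise, but no label gives an exercise state of any mouse. The values were deposited intensities with a median of 671 to 699 per array, a lowest value of 86.5 to 92.3 and an upper limit of 44145 to 45552 that at least 51 probe sets had reached on each array. Precision was limited by the number of arrays, 3 and 4. The mouse numbers differ between arrays. limma's p-values of single probe sets measure the spread between these arrays, in which mouse and hybridization day are mixed. Camera's p-values set a list's genes against the other genes at a fixed correlation and do not measure the spread between mice.

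The probe set of Nos3 (1422622_at) read 1145, 1414 and 1135 on the arrays labelled knockout M4, M10 and M140. It read 791, 1163, 872 and 1058 on wild-type M23, M125, M128 and M158. The means were 1231 ± 157.9 (SD, n = 3) and 971 ± 170 (SD, n = 4), a log2 difference of 0.35 ± 0.15 (SE) with an adjusted p of 0.42 by limma and an exact two-sided permutation p of 0.171. The targeted transcript was therefore not lower on the arrays labelled knockout. The position of this probe set relative to the disrupted part of the gene is not given in the sources used here, so that its level does not check the labels. Directions below are those of the arrays labelled knockout against the arrays labelled wild type.

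Genes of the fetal heart programme and of hypertrophy shifted higher as a list on the arrays labelled knockout, and genes of mitochondrial fatty acid oxidation shifted lower, by camera with a preset correlation. Neither call held with an estimated correlation (adjusted p = 0.242 for each) or by fry (adjusted p = 0.0863 and 0.103). Ankrd1, a stress-inducible cardiac ankyrin repeat protein, read 43675 ± 2670 (SD, n = 3) against 18551 ± 5426 (SD, n = 4). Ppargc1a, a coactivator of mitochondrial and oxidative genes, read 907 ± 215 (SD, n = 3) against 3717 ± 544 (SD, n = 4) on its probe set 1456395_at. This probe set differed most (log2 -2.03), and the others of the gene by -0.50 to -0.81. No single probe set passed an adjusted p of 0.05 by limma. Of 13836 tested probe sets, 0 passed, 21 had an adjusted p under 0.10 (12 higher and 9 lower), and 1636 had an unadjusted p under 0.05 (909 higher and 727 lower). Of 8869 tested genes, 0 passed and 1077 had an unadjusted p under 0.05 (598 higher and 479 lower). With limma array weights in the same fit, 619 probe sets and 402 genes passed an adjusted p of 0.05. Without knockout M10 the counts were 74 and 53, and without knockout M140 they were 27 and 14. The mean of all probe sets of a gene, in place of the brightest one, gave 11 genes. The 3 knockout arrays lay wholly above or below the 4 wild-type arrays for 9.3% of tested probe sets, against 5.71% by chance.

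The fetal and hypertrophy list had 12 tested members of 16. Their median log2 difference was 1.11, and 11 of the 12 were higher (camera adjusted p = 2.6e-07; adjusted p = 0.242 with an estimated correlation). After adjustment over the list alone, 9 members passed, all higher; over all genes tested, 0 passed. Acta1, the skeletal muscle actin of the fetal ventricle, read 22144 ± 14215 (SD, n = 3) against 3104 ± 1680 (SD, n = 4), a log2 difference of 2.73 ± 0.61 (adjusted p = 0.209). Myh7, the slow myosin heavy chain, differed by 2.43 ± 0.76 on the log2 scale (adjusted p = 0.299). Nppa and Nppb, which encode the atrial and brain natriuretic peptides released by loaded heart muscle, differed by 1.80 ± 0.49 (adjusted p = 0.259) and 1.38 ± 0.55 (adjusted p = 0.392). The wild-type arrays varied widely. Nppb read 33621 and 35703 on wild-type M23 and M158, both of day 4, against 8385 and 8423 on wild-type M125 and M128. Myh7 ran from 2002 on wild-type M128 to 30422 on wild-type M23. Ankrd1 differed by 1.28 ± 0.21 (adjusted p = 0.138), and its other probe set 1420991_at by 2.15 ± 0.28 (adjusted p = 0.0769). Xirp1, an actin-binding repeat protein of the intercalated disc, differed by 0.95 ± 0.20. Pfkp, Fhl1 and Rcan1 also passed over the list alone, at 1.22, 0.67 and 0.99. Each of these 9 genes except Rcan1 read higher on all 3 knockout arrays than on all 4 wild-type arrays. Ankrd1, Nppa, Nppb and Myh7 were at the upper limit of the scale on 2 of 3 knockout arrays and on 0 wild-type arrays, so that their differences are understated. Within the single hybridization day that held both groups, the median of knockout M140 minus wild-type M128 over the list was 1.66, and Acta1, Myh7, Nppb and Xirp1 differed by 4.15, 4.43, 2.43 and 1.47. Nppa and the other natriuretic transcripts are also abundant in atrial muscle, and the atrial myosin light chain Myl7 read 17557 on knockout M10 and 16097 on wild-type M125, 2926 on wild-type M128, 1207 on knockout M4 and between 356 and 407 on the other 3 arrays.

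**Figure D1:**
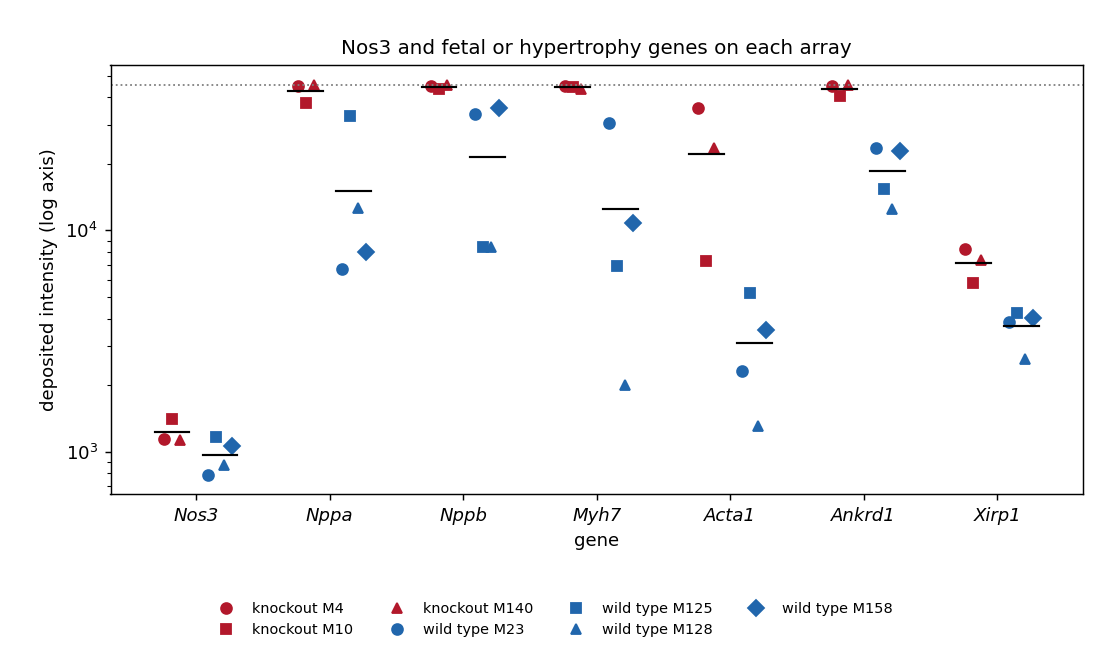
Deposited intensity on a log axis for Nos3 and 6 genes of the fetal and hypertrophy list; each point is 1 array, red for knockout and blue for wild type, black lines are group means, and the dotted line is the highest value of any array (45552). Nos3 overlaps between the groups, whereas the 3 knockout arrays lie above all 4 wild-type arrays for the other 6 genes, with several knockout points at the upper limit.

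Myh6, the adult myosin heavy chain, and the brightest probe set of Atp2a2, the calcium pump of the sarcoplasmic reticulum, were at the upper limit on all 7 arrays and give no fold. Another probe set of Atp2a2 below the limit, 1427250_at, read 17759 in the knockout mean and 17106 in the wild-type mean, a log2 difference of 0.059 ± 0.091 (SE; adjusted p = 0.866). The adult sarcomere list had a median log2 difference of -0.01 over 22 members (camera adjusted p = 0.344), and 12 of these members were at the limit on at least 1 array. This median is the value of members such as Myh6 at the limit on all 7 arrays, so that it does not show an unchanged list. The list's mean was 0.11. All 3 knockout arrays lay above all 4 wild-type arrays for 5 members and below them for 0. Over all tested genes, 10.2% lay apart one way or the other. The calcium handling and ion channel list had a median of -0.03 over 20 members (camera adjusted p = 0.298). Pln, the inhibitor of that pump, read 23283 ± 1835 (SD, n = 3) against 37953 ± 2876 (SD, n = 4) on its probe set 1423359_at, a log2 difference of -0.70 ± 0.08 (adjusted p = 0.0769). Its 2 brighter probe sets were at the limit on 6 and on 2 arrays. The second, 1450952_at, read 44940 in the knockout mean and 45123 in the wild-type mean, against 44944 and 45135 for Myh6 at the limit. Both probe sets differed by -0.01 and, so close to the limit, give no fold.

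Of 29 fatty acid oxidation genes 24 were tested, and 10 had an unadjusted p under 0.05, all lower. The median log2 difference was -0.38 (camera adjusted p = 4.0e-08; adjusted p = 0.242 with an estimated correlation). After adjustment over the list alone, 8 passed, all lower; over all genes tested, 0 passed. Mlycd, which controls malonyl-CoA and with it fatty acid entry into mitochondria, differed by -0.68 ± 0.16 (adjusted p = 0.224). Decr1, needed for unsaturated fatty acids, differed by -0.39 ± 0.11 (adjusted p = 0.259), and Acads, the short-chain acyl-CoA dehydrogenase, by -0.71 ± 0.20 (adjusted p = 0.266). Cpt2, Acadvl, Acaa2, Cd36 and Acot1 also passed over the list alone, at -0.63, -0.27, -0.60, -0.24 and -1.05. Pdk4 and Ucp3, a pyruvate dehydrogenase kinase and a mitochondrial carrier induced by fatty acids, read 9250 ± 5005 and 616 ± 61 (SD, n = 3) against 20473 ± 14054 and 982 ± 374 (SD, n = 4), with overlapping groups and adjusted p of 0.583 and 0.446. Within the day that held both groups the list's median was -0.39, and Acads, Pdk4 and Ucp3 differed by -0.40, -2.10 and -1.02.

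The respiratory chain and ATP synthase list shifted lower, with a median log2 difference of -0.03 over 65 tested members of 71, 11 of them lower at an unadjusted p under 0.05 and 0 past adjustment over the list alone (camera adjusted p = 7.3e-05; adjusted p = 0.242 with an estimated correlation). Of the 65, 28 were at the upper limit on at least 1 array. The median was -0.019 with quantile normalization, -0.095 with probe sets below the limit (camera adjusted p = 1.3e-06), -0.064 with all probe sets of each gene and -0.078 with their mean (adjusted p 2.2e-08 to 0.242 over all alternatives). Cox7a1, a muscle subunit of cytochrome oxidase, differed by -0.36 ± 0.07 (adjusted p = 0.186), Ndufb2 of complex I by -0.61 ± 0.13 (adjusted p = 0.196) and Uqcrq of complex III by -0.47 ± 0.12 (adjusted p = 0.254). The other 3 probe sets of Uqcrq were dim and differed by -0.12 to 0.09. The citric acid cycle and pyruvate dehydrogenase list had a median of -0.11 over 21 members (camera adjusted p = 0.0138; adjusted p = 0.527 with an estimated correlation). Its member Suclg1, a subunit of succinyl-CoA ligase, was the 1 that passed over the list alone, at -0.48 ± 0.09. Suclg2 differed by -0.33, and the 2 probe sets of Sdha by -0.29 and 0.25. Within the day that held both groups the medians were -0.03 for the respiratory chain and 0.01 for the citric acid cycle, and Uqcrq and Suclg2 differed by -0.24 and -0.20. The call of the citric acid cycle ended without knockout M10 (adjusted p = 0.0682) or wild-type M158 (adjusted p = 0.0653). Its median was -0.071 without M10, -0.072 without M158 and -0.075 without wild-type M23. It also ended without M23 and M158, the arrays with the lowest ratio of 5' to 3' Gapdh signal (median -0.076, adjusted p = 0.120), and without M10 and M125, those with the most Myl7 (-0.065, adjusted p = 0.137). It held with the Gapdh ratio (-0.081, adjusted p = 0.0130) or Myl7 (-0.10, adjusted p = 0.0193) as a covariate.

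**Figure D2:**
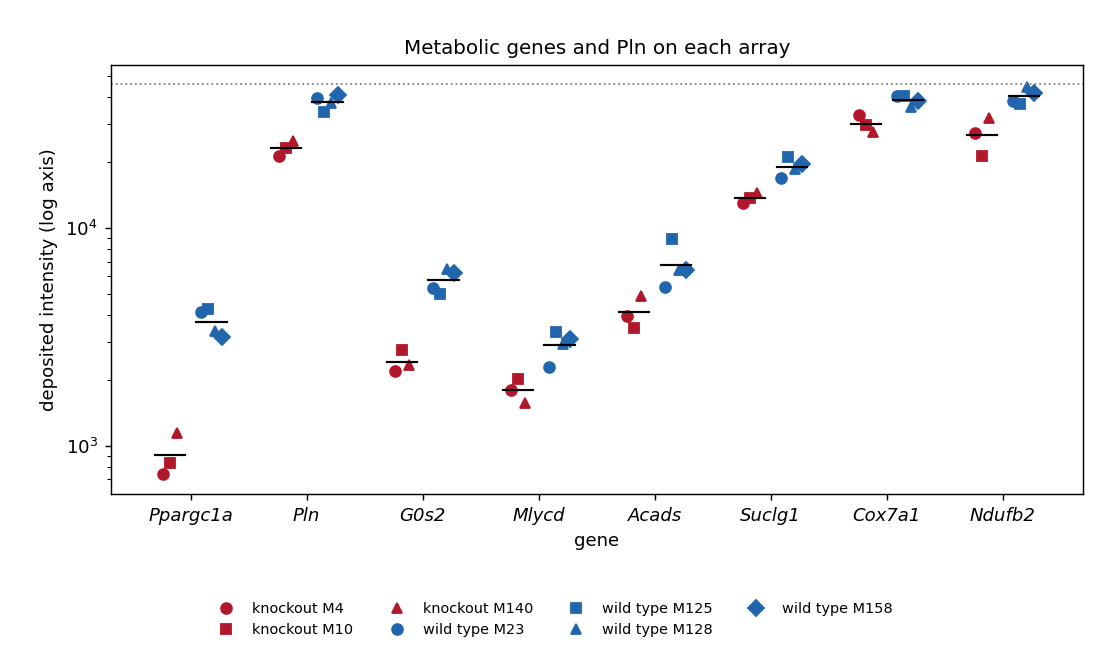
Deposited intensity on a log axis for Ppargc1a (1456395_at), Pln (1423359_at) and 6 metabolic genes; each point is 1 array, red for knockout and blue for wild type, black lines are group means, and the dotted line is the highest value of any array (45552). For each of these genes the 3 knockout arrays lie below all 4 wild-type arrays.

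Ppargc1a had the smallest p of all probe sets at 1456395_at, with a log2 difference of -2.03 ± 0.18 and an adjusted p of 0.0531; it was picked out after its values were seen. Its other 4 probe sets read lower as well, by -0.50 to -0.81 on the log2 scale, with adjusted p of 0.29 to 0.377. The mean of all its probe sets differed by -0.97. Ppargc1a lies on chromosome 5, as does Nos3, and an effect of donor-strain DNA on this probe set was not tested. Among the genes with the smallest p in the lower direction, G0s2, an inhibitor of fat breakdown, read 2435 ± 289 (SD, n = 3) against 5751 ± 724 (SD, n = 4), a log2 difference of -1.23 ± 0.15 (adjusted p = 0.0769). Cenpv, Pla2g5 and Cryba4 had the same adjusted p and differed by -0.93, -1.14 and -0.65. Fmc1, Entpd5, Snx16, Nmb, Pigu and Dut followed, at -0.71, -0.89, -0.58, -0.57, -0.73 and -1.12 (adjusted p between 0.115 and 0.138). Dut differed by -1.74 within the day that held both groups. In the higher direction, Adamts1, a secreted protease that cleaves matrix proteoglycans, read 2966 ± 449 (SD, n = 3) against 1161 ± 238 (SD, n = 4), a log2 difference of 1.35 ± 0.18 (adjusted p = 0.0769). Wdfy1, Gtpbp4, Ehd4, Elovl1 and Tmbim1 had the same adjusted p and differed by 0.66, 0.90, 0.88, 0.71 and 0.79. Cdv3, Tmem176a, Tent5c and Osmr, the oncostatin M receptor, followed at 1.01, 0.75, 1.48 and 0.65 (adjusted p between 0.0958 and 0.132). Elovl1 and Pigu, like Sdha, Uqcrq, Hbb-b2, Acaa2, Serpinh1 and H2-Aa, were read by probe sets of a kind that can cross-hybridize with related transcripts.

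The extracellular matrix and fibrosis list shifted higher, with a median log2 difference of 0.48 over 35 tested members of 41, of which 7 were higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 1.4e-05; adjusted p = 0.702 with an estimated correlation). One knockout array stood apart: the mean deviation of the list was 0.56 on M4 and 0.78 on M140 but -0.45 on M10, below every wild-type array (-0.31 to -0.14). Ccn2, the connective tissue growth factor, read 31177 ± 13369 (SD, n = 3) against 7907 ± 2299 (SD, n = 4), a log2 difference of 1.91 ± 0.36 (adjusted p = 0.155), and was the 1 member that passed over the list alone. Fn1, fibronectin, differed by 0.77 ± 0.19 and Lox, the collagen cross-linking oxidase, by 1.33 ± 0.41 (adjusted p = 0.248 and 0.294). The collagen genes Col1a1 and Col3a1 had overlapping groups, and Col3a1 read 17213 and 19869 on knockout M4 and M140, 1691 on knockout M10 and 4197 to 7594 on the wild-type arrays. Serpinh1, a collagen chaperone, was the 1 member lower at an unadjusted p under 0.05, at -0.78. Without knockout M140 the list's call ended (median 0.24, adjusted p = 0.107), and without knockout M10 its median was 0.82. Within the day that held both groups it was 1.10, and Col1a1 and Col3a1 differed by 0.996 and 2.22.

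**Figure D3:**
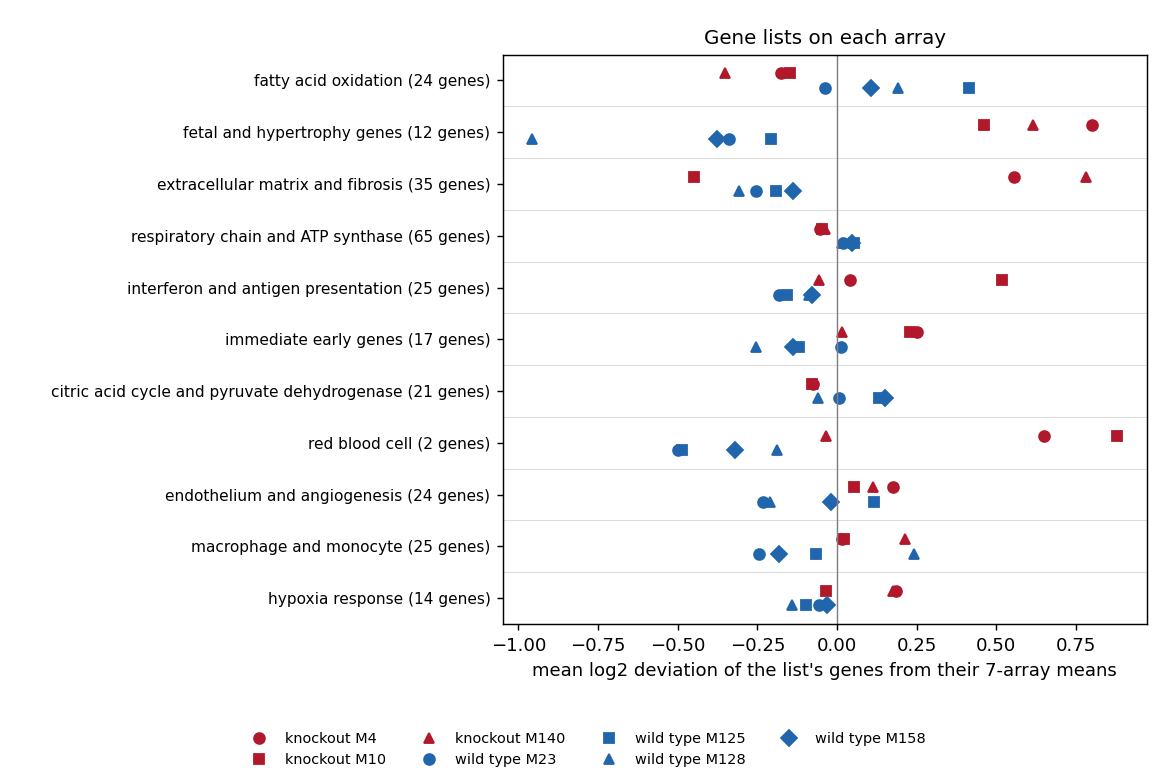
Mean log2 deviation of each list's genes from their means over the 7 arrays, for the 11 lists past the threshold; each point is 1 array, red for knockout and blue for wild type. The fetal and hypertrophy genes separate the groups, the extracellular matrix genes place knockout M10 at -0.45 apart from M4 and M140, and the interferon genes place M10 at 0.52.

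Interferon and antigen presentation genes had a median log2 difference of 0.18 over 25 members (camera adjusted p = 0.00130; adjusted p = 0.756 with an estimated correlation), with 7 higher and 1 lower at an unadjusted p under 0.05. Ifit3, an interferon-induced antiviral protein, differed by 0.98 ± 0.18 (adjusted p = 0.154), Ifit2 by 0.82 and Ifi27l2a by 0.87; the member lower at that p was the chemokine Cxcl9, at -0.30. Of these, Ifit3 alone passed over the list alone. Within the day that held both groups these 3 higher genes differed by 0.89, 0.83 and 0.20. The call was lost with array weights (median 0.15, adjusted p = 0.103) and without knockout M10 (median 0.09, adjusted p = 0.424), it was lost without M10 and M125 (0.10, adjusted p = 0.608), the median was 0.27 without knockout M4 or M140, and it was 0.00 within the day that held both groups. Markers of macrophages and monocytes had a median of 0.10 over 25 members, with 5 higher and 1 lower, H2-Aa, at an unadjusted p under 0.05 (camera adjusted p = 0.0212; adjusted p = 0.702 with an estimated correlation). Fcgr3, Cd163 and Csf1r, receptors of these cells, differed by 0.54, 0.49 and 0.49, and the first 2 passed over the list alone. The macrophage call ended with the 60th percentile filter (median 0.12, adjusted p = 0.0683). It also ended without knockout M140, wild-type M23, M125 or M158 (medians 0.03, 0.05, 0.13 and 0.13; adjusted p of 0.398, 0.133, 0.0575 and 0.0675), and the median was 0.17 without knockout M10, 0.23 without wild-type M128 and -0.04 within the day that held both groups, where Cd163 differed by 0.75. This list moved with the arrays of low Gapdh ratio: without M23 and M158 the median was -0.055 (adjusted p = 0.621). With the Gapdh ratio as a covariate the median was 0.030 (adjusted p = 0.339). The ratio is limited by its 3' probe set at the upper limit, and a low ratio cannot be told apart from day 4. Without M10 and M125 it was 0.15 (adjusted p = 0.0655). The red blood cell list rested on 2 tested members of 10, Alas2, of haem synthesis, at 1.33 and the haemoglobin chain Hbb-b2 at 0.41 (camera adjusted p = 0.0141; adjusted p = 0.401 with an estimated correlation). Its call ended without knockout M10 (median 0.68, adjusted p = 0.0682), without M23 and M158 (0.84, adjusted p = 0.120), without M10 and M125 (0.64, adjusted p = 0.141) and with all probe sets (0.41, adjusted p = 0.0823), its median was 0.15 within the day that held both groups, and the other probe set of Hbb-b2 differed by -0.04. Within that day Alas2 differed by 0.29 and Hbb-b2 by 0.016.

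Endothelial and angiogenic genes had a median log2 difference of 0.16 over 24 members, 5 of them higher at an unadjusted p under 0.05 (camera adjusted p = 0.0150; adjusted p = 0.70 with an estimated correlation). Icam1, an adhesion molecule, and Vwf, von Willebrand factor, passed over the list alone at 0.55 ± 0.11 and 1.26 ± 0.30, and Ptgis, prostacyclin synthase, differed by 0.79. The endothelial call ended without M23 and M158 (median 0.12, adjusted p = 0.212) and with the Gapdh ratio as a covariate (0.12, adjusted p = 0.152). It also ended without single arrays of a higher Gapdh ratio (below), so that its loss neither shows a link to RNA quality nor rules one out. The mean deviation of the list was -0.23 on M23 and -0.02 on M158, against -0.21 on M128, whose ratio was higher. The immediate early genes had a median of 0.24 over 17 members (camera adjusted p = 0.0138; adjusted p = 0.242 with an estimated correlation), with Btg2, Egr1 and Ier3 at 0.55, 0.99 and 0.44 and the other probe set of Btg2 at -0.17. Egr1 differed by 0.52 without knockout M4 and Ier3 by 0.29 without knockout M140. Within the day that held both groups Btg2, Egr1 and Ier3 differed by 0.11, 0.19 and 0.82. The immediate early call ended with array weights (median 0.14, adjusted p = 0.0647) and without M10 and M125 (median 0.23, adjusted p = 0.120). The hypoxia response list had a median of 0.21 over 14 members (camera adjusted p = 0.0212; adjusted p = 0.245 with an estimated correlation), with P4ha2 at 0.60, Vegfa at 0.38 and the glucose transporter Slc2a1 at 0.31. Within that day these 3 differed by 0.77, 0.016 and 0.42, and Ptgis of the endothelial list by 1.31. With all probe sets of each gene the hypoxia median was 0.11 and the endothelial median 0.10. The medians of the 3 lists within the day were 0.32, 0.30 and 0.20. The endothelial call ended without knockout M140, wild-type M23 or M128 (adjusted p of 0.0611, 0.107 and 0.0919), the immediate early call without knockout M10 or wild-type M128 (0.0710 and 0.0637), and the hypoxia call without knockout M140, wild-type M125 or M128 (0.213, 0.0511 and 0.0683).

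The other 20 lists did not pass (camera adjusted p between 0.344 and 0.953). Median log2 differences were 0.08 for glycolysis and glucose uptake, 0.00 for nitric oxide and cGMP signalling without Nos3, 0.07 for adrenergic and renin-angiotensin genes, and -0.04 for antioxidant and xenobiotic defence. They were 0.02 for heat shock and chaperones, 0.02 for cell death, 0.02 for proteasome and muscle atrophy, and -0.01 for ribosomal proteins. They were 0.00 for the circadian clock, -0.01 for the cell cycle and -0.06 for the genes flanking Nos3. Among cell type markers they were 0.10 for smooth muscle, 0.05 for neutrophils and mast cells, 0.08 for lymphocytes, 0.01 for adipocytes, -0.06 for atrial cardiomyocytes, 0.01 for skeletal muscle, 0.07 for mesothelium, -0.05 for nerve and Schwann cells, and -0.04 for lung and liver. Camera's direction was opposite to the sign of the median for the adult sarcomere, cell cycle, ribosomal protein, atrial, adipocyte and skeletal muscle lists. The mean had the opposite sign to the median for these lists except skeletal muscle, and for the antioxidant and the lung and liver lists.

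None of the 11 calls held with an estimated correlation (lowest adjusted p = 0.242), and fry, which tests whether a list's genes move one way on balance, called 1 list, the respiratory chain (adjusted p = 0.00792). With hybridization day as a fixed block, which compares the single pair of arrays of day 1 and takes its spread from the pairs of days 3 and 4 (2 residual degrees of freedom), 4 of the 11 calls held: fetal and hypertrophy (adjusted p = 1.8e-07), extracellular matrix (2.1e-07), fatty acid oxidation (4.1e-06) and endothelial genes (0.0130). The other 7 ended, with adjusted p from 0.0571 for the hypoxia response and 0.133 for the respiratory chain to 0.862. With the day as a random block, chosen after the data were seen, the 11 calls held at the preset correlation (camera adjusted p up to 0.0335, for the citric acid cycle). That fit also compares arrays of days that held 1 group only, so that it does not part day from genotype. With Myl7 as a covariate the 11 calls held. With the Gapdh ratio 9 did, all but the macrophage and endothelial calls, but this ratio follows the 5' intensity and measures RNA quality only in part. The ratio of 5' to 3' Gapdh control intensity was 0.0978 on wild-type M23 and 0.34 on wild-type M158, both of hybridization day 4. It was 0.521 to 0.777 on the other 5 arrays (exact two-sided permutation p = 0.514 between the groups, over 11 array measures with a lowest exact p of 0.0571, or 0.629 after Benjamini-Hochberg adjustment). The 3' probe set was at or near the upper limit on every array (44145 to 45552, with 45466 on M158). Each ratio is therefore an upper bound that follows the 5' intensity, which was 4456 on M23, 15460 on M158 and 23125 to 34559 on the other 5. The 5' to 3' ratio of beta-actin was also lowest on M23 (0.312) and M158 (0.371), against 0.517 to 0.833 on the other 5. The control probe set BioB-M read 5288 on M23 and 7826 on M158, against 1054 to 1309 on the other 5. These differences cannot be told apart from day 4.

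**Figure D4:**
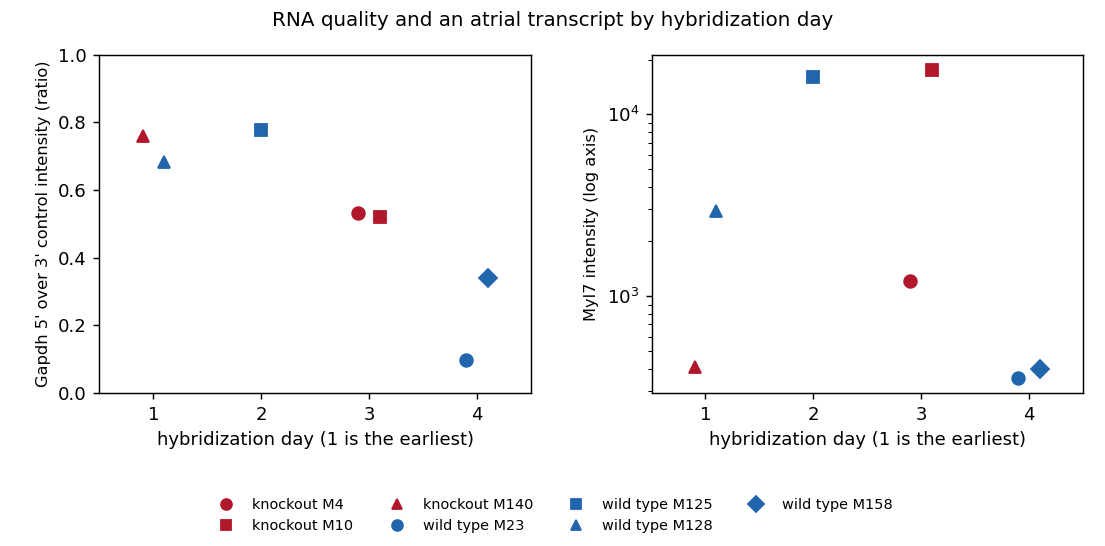
Ratio of the 5' to the 3' Gapdh control probe set (left) and intensity of the atrial transcript Myl7 on a log axis (right) by hybridization day, coded 1 to 4; each point is 1 array, red for knockout and blue for wild type. Wild-type M23 and M158, of day 4, have the lowest ratios (0.0978 and 0.34), and knockout M10 and wild-type M125 the highest Myl7 (17557 and 16097). The 3' Gapdh probe set is at or near the upper limit on every array, so that each ratio is an upper bound.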

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

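The wild-type values of each named gene, each list and each array measure were searched for 1 of the 4 arrays far from the other 3. Chance gives about 1 in 20, here 5.2, and 4 were found. Groups of 3 knockout arrays were not searched. The gap to the nearest array as a share of the whole range, on the log2 scale for genes, was 0.901 for Ifi27l2a, where M128 read 4824 and the others 2750 to 2908. It was 0.879 for Slc2a1, where M23 read 3766 and the others 2822 to 2923. It was 0.842 for Elovl1, where M128 read 1235 and the others 1362 to 1387. It was 0.830 for Hbb-b2, where M128 read 2065 and the others 1722 to 1776. No explanation was tested for these 4 genes.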

How the results depend on the processing

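Settings chosen after the data were seen were the random day block, for lists the day block, eBayes without trend, array weights and the mean of all probe sets, then normexp, both covariates, probe sets below the limit, 5 further settings for Nos3, and leaving out M23 with M158 or M10 with M125. At an adjusted p of 0.05 limma called 0 probe sets and 0 genes (1636 and 1077 at an unadjusted p under 0.05). Array weights, which gave knockout M4 3.81 and wild-type M128 0.373, gave 619 and 402. A threshold of 0.10 gave 21 and 11, and an unadjusted p under 0.05 with a 1.5-fold difference 495 and 308. The 60th percentile filter gave 1 probe set, of Ppargc1a, with 9303 tested in place of 13836. The fixed day block and leaving out M23 with M158 each gave 1 probe set and 1 gene, Nppb, and leaving out M10 with M125 gave 2 and 2, Comp and Itgbl1. The mean of all probe sets of a gene gave 11 genes, Ankrd1, Cenpv, G0s2, Tmem176a, Wdfy1, Adamts1, Cryba4, Ehd4, Pla2g5, Ppargc1a and Tmbim1. Leaving out 1 array gave 0 to 74 probe sets and 0 to 53 genes: 74 and 53 without knockout M10, 27 and 14 without knockout M140, and 0 without each other array. Apart from the looser thresholds and the smaller number of tests, the cause was not tested.

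Of 11 lists, 0 were called with an estimated correlation and 1 by fry. With the fixed day block 7 were called, 4 of them among the 11. There were 9 with array weights, 10 with the 60th percentile filter, 7 without M23 and M158, 6 without M10 and M125, and 7 to 12 when 1 array was left out (7 without knockout M10 or M140). An estimated correlation and fry leave the medians as they were and ended the calls of fatty acid oxidation (-0.38, adjusted p = 0.242 and 0.103), the fetal genes (1.11, 0.242 and 0.0863) and the extracellular matrix (0.48, 0.702 and 0.495). Fatty acid oxidation (-0.47 to -0.30, adjusted p 7.4e-11 to 0.242) and the fetal genes (0.95 to 1.66, 3.1e-10 to 0.242) passed in the other 24 of 26 alternatives. All of these kept the preset correlation of 0.01, so that they do not test it. The estimated correlation was 0.17 for fatty acid oxidation, 0.20 for the fetal genes and 0.48 for the extracellular matrix. At a simulated correlation of 0.2, the unchanged fatty acid oxidation list had an unadjusted camera p under 0.05 in 43% of simulations. The extracellular matrix (0.24 to 1.10, 8.9e-19 to 0.702) passed in 23; when 1 array was left out it ran from 0.24 without knockout M140, where its call ended, to 0.82 without knockout M10. The cause was not tested.

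Nos3 did not pass in any of 21 alternatives (log2 difference 0.24 to 0.44, adjusted p 0.265 to 0.877). Of 1234 values of 59 other named genes, 1233 kept their direction, and 44 of the genes passed in at least 1 alternative. Apart from those fixed by name, these genes were chosen by their p on the same arrays. A kept direction was thus largely set beforehand and is no support. Col3a1 reversed without knockout M140 (-0.067) and read 1.70 without knockout M10; the cause was not tested. Leaving out 1 array also moved by over 1.5 times Egr1 and Ier3, Sdha (-0.17 without M140), Suclg2 (-0.21 without M158), Lox (0.84 without M140), Hbb-b2 (0.26 without M10), Pdk4 and Ucp3 (-0.59 and -0.38 without M125), Col1a1 (0.22 without M140, 0.77 without M10) and Col3a1 (0.037 without M4). The background (lowest values 86.5 to 92.3) shrinks differences of dim probe sets and the upper limit those of bright ones.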

Other observations

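Of the tests below, the counts over all 35 splits and both tests of gene order were set before their results were seen; the splits that keep the pairs of days 3 and 4 together, all tests of technical explanations and the genes of the next sentences were chosen after. In lists that were not called, single members passed adjustment over their list alone, while 0 genes passed over all genes tested. Npr3, the clearance receptor of natriuretic peptides, differed by 1.15 on the log2 scale, higher on each array labelled knockout than on each labelled wild type. In the antioxidant list the glutathione peroxidase Gpx3 and the thioredoxin reductase Txnrd1 differed by 1.30 and 0.71, and the glutathione transferase Gstt1 by -0.54. Lcn2, lipocalin 2, differed by 0.83 with overlapping groups. Prkag2, a subunit of the AMP-activated kinase and a neighbour of Nos3, differed by 0.92. Among probe sets with an adjusted p under 0.10 not yet named, Cp, ceruloplasmin, differed by 1.06, Hsdl2 by -1.07, Ankrd24 by -0.73 and Galm by -0.63. Prkag2, Ankrd24 and Galm were read by probe sets that can cross-hybridize.

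The higher fetal and hypertrophy genes were set against 3 technical explanations. The median was 1.07 without the day 4 arrays of low Gapdh ratio and 1.15 with Myl7 as a covariate (1.22 without M10 and M125), with the camera call kept (adjusted p 3.1e-10 to 0.242 over all alternatives), which argues against RNA loss on day 4 and atrial tissue as the whole cause. Hybridization day and genotype cannot be told apart: with the day as a fixed block the median was 1.66, but this compares 1 array with 1 (knockout M140 and wild-type M128, the lowest wild-type array on this list at -0.96), with a spread taken from days 3 and 4. Of the 35 splits 1, the real one, gave a camera p as small (1.5e-08, lowest other 3.3e-07). The smallest share these splits can give is 0.0286, and it was not adjusted for the several lists and counts that were split. They also take arrays of 1 day as independent, so that chance is not excluded. The genotype stays open and untested.

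The lower fatty acid oxidation genes had a median of -0.37 without the day 4 arrays, with the camera call kept (adjusted p 7.4e-11 to 0.242 over all alternatives), which argues against RNA loss on day 4 as the whole cause. A lower share of heart muscle cells would lower their other genes alike. The 28 sarcomere and calcium handling genes below the upper limit had a median of -0.013 (bootstrap 95% interval over genes -0.10 to 0.079), against -0.38 for the list. A loss common to these genes was therefore not seen. The interval does not cover the spread between mice. Members of these lists moved either way (Des 0.90, Ckm -0.66, Kcnd2 -0.70), so that a lower share stays open. Day and genotype cannot be told apart, since the median of -0.39 with the fixed day block rests on the same pair of single arrays. Chance cannot be excluded, since 2 of the 35 splits gave a camera p as small: the real one (1.2e-09) and the one that moves wild-type M23 to the knockout arrays (9.8e-11). The genotype stays open and untested.

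Extracellular matrix genes were higher on knockout M4 and M140 but not on M10. The median of M10 minus M4, of 1 day and chip lot, over the list was -0.97 (bootstrap 95% interval over genes -1.17 to -0.59). The pattern was picked for this difference, so that its size is no independent test. A shift shared by the arrays of a day would leave these 2 alike and cannot by itself part them. Wild-type M125, with about as much Myl7 as M10, differed from the other wild-type arrays by 0.056 (bootstrap 95% interval over genes -0.14 to 0.22), where M10 differed from M4 and M140 by -1.03, but 1 array leaves atrial tissue open. For the shift of the list between the groups chance cannot be excluded: 11 of the 35 splits gave a camera p as small (1.3e-06, lowest other 2.0e-17 with M4, M140 and wild-type M158 together). A difference between the knockout mice themselves may underlie the pattern and was not tested.

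Of the 35 splits 1, the real one, gave as many probe sets (1636, highest other 1509) and genes (1077, highest other 948) with an unadjusted p under 0.05, and with array weights 1, the real one, gave 619 probe sets (highest other 88). These splits take the 7 arrays as exchangeable. Even on that footing the smallest share they can give is 0.0286, unadjusted for the several lists and counts that were split, so that chance is not excluded. The real split keeps the pairs of days 3 and 4 together, M4 with M10 and M23 with M158, and parts the pair of day 1, M140 and M128; 7 of the 35 splits keep the first 2 pairs together. Among these the real one had the most probe sets and genes with an unadjusted p under 0.05 (highest other 1258 and 742). It also had the most probe sets with array weights (highest other 88) and the most lists called (highest other 9). Its camera p was the smallest for the fetal list (lowest other 2.0e-06), fatty acid oxidation (6.4e-07) and the extracellular matrix (2.0e-04). However, 7 splits are too few for a share under 0.05. The split with 1509 joined knockout M10 with wild-type M125 and M128, the 3 arrays highest in Myl7, which points to a structure of the samples besides the groups. The 0 probe sets that limma called without weights at an adjusted p of 0.05, where 1636 had an unadjusted p under 0.05, are reached by all 35 splits by construction (highest other 0), so that their count says nothing about chance. For the number of lists called chance cannot be excluded: 2 of the 35 splits gave as many (11, highest other 12 with M4, M140 and M158).

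A hypothesis was that DNA of a donor strain around Nos3 shifts its neighbours. Among up to 50 tested genes on each side, in the gene order of GRCm38.p6, 11 of 83 had an unadjusted p under 0.05 (13.3%), against 12.1% of the other genes (one-sided Fisher exact p = 0.428; odds ratio 1.11, 95% interval 0.527 to 2.11). Too few genes keep an odds ratio of 2 open, so that such a segment and none cannot be told apart. Another hypothesis was that genes with an unadjusted p under 0.01 cluster along the chromosomes. The fullest window of 50 tested genes held 7, on chromosome 9, and a share of 0.757 of 10000 shuffles of gene order reached as many, so that clustering beyond chance was not seen.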
